A study of Mus musculus with 2 samples.

How the data were processed

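H3K4me3 ChIP-seq libraries came from whole midbrain of mouse embryos aged 14.5 days, pooled from 24 embryos (replicate 1) and 34 embryos (replicate 2) of mixed sex. Both replicates belong to 1 group, as the labels state, and the labels give no other condition. No control library was analysed here.

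Alignment to mm10 and peak calling were done by the authors; the aligner, the peak caller, their versions and the normalization are not given in the sources used here. Each of the 4 deposited lists is in narrowPeak format, as the accompanying text files state: peaks of replicate 1, peaks of replicate 2, peaks called on both together (pooled, 28426 peaks), and replicated peaks derived from the other lists. The deposited enrichment value per peak is a ratio, taken as fold enrichment over the control; this unit was inferred from the narrowPeak layout and from values that all exceeded 1, since the labels name a possible control without saying how it was used. The deposited significance values are −log10 p and −log10 q per peak, inferred in the same way. The deposited summit column is an offset in bp from the peak start. Every peak had a −log10 p of at least 2, and 3.16% of replicate 1 peaks and 5.48% of replicate 2 peaks had a q over 0.05.

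The replicated list was tested against the others. All 21806 replicated peaks stood in the pooled list with the same values. All 20810 pooled peaks that shared at least 50% of either peak with a peak of both replicates were in it, and so were 996 peaks (4.57%; median fold enrichment 3.50) that did not, of which 965 shared no base with at least 1 replicate. How these 996 were chosen is not given in the sources used here, and they were kept.

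Read depth per library is unknown, so the precision of shares rests on the number of peaks or genes, as Wilson 95% intervals that cover counting error only. With 2 replicates, errors of widths are the SD of both values. The list median of a replicate covers the genes marked in the list of that replicate.

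The annotation was GENCODE M21 on the same build. Promoter CpG content was observed over expected CpG in the genome sequence within 500 bp on either side of the gene 5′ end. Other transcript starts of a gene, at which it could also be marked, did not enter this value. Peaks on unlocalized and unplaced scaffolds were left out of the comparisons with genes. A peak was at a TSS when at least 1 bp lay within 1 kb of the start of any transcript. The 21911 protein-coding genes on chromosomes 1 to 19, X and Y were analysed. A gene was marked when a peak met its TSS window. Its promoter domain was the widest run of peaks at most 500 bp apart that met the window, and its strength was the highest fold enrichment there. Random placements moved all peaks of a list 20 times within their chromosomes.

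The 24 gene lists were midbrain and isthmus patterning, dopaminergic lineage, GABAergic neurons, glutamatergic neurons, pan-neuronal, late synaptic maturation, neural progenitors and radial glia, cell cycle, housekeeping, oligodendrocyte lineage, astrocytes, ependyma and choroid plexus, cranial motor and serotonergic neurons, microglia, endothelium and pericytes, meninges and mesenchyme, erythroid, Hox clusters, forebrain patterning, liver, skeletal and cardiac muscle, spermatogenesis, pluripotency, and olfactory and vomeronasal receptors. All 1840 symbols matched the annotation. Lists, thresholds, tests, the naming rule and the alternatives were chosen before the data were examined, except where the text says otherwise. The share marked was compared with all other protein-coding genes by a two-sided Fisher exact test per list, with Benjamini-Hochberg adjustment over the 24 lists. The median width of a list was compared with 100000 random lists of as many marked genes (two-sided permutation test, smallest p 2e-05), adjusted over the 20 lists with at least 5 marked genes. An adjusted p under 0.05 was called. Fold enrichment per list is described by medians.

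Named genes were the 12 widest promoter domains with a width in the top 5% in both replicates, the 12 strongest promoter peaks, for each list the 2 widest marked genes and the first 2 unmarked genes in alphabetical order, and the 6 strongest peaks more than 5 kb from every TSS. Genes outside this rule are stated as chosen after their values were seen.

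Alternatives were an overlap of 50% of the peak or of both peaks, a −log10 q of at least 5, equal numbers of peaks, TSS windows of 500 bp and 2 kb, gene 5′ ends alone, peak summits, the pooled list, each replicate's list alone (without the other replicate), merging of overlapping peaks only or of peaks up to 1 kb apart, −log10 p in place of fold enrichment, and random lists matched on promoter CpG content in 10 bins. Chosen after seeing the data were replicated peaks sharing at least 1 bp with both replicates, and 1 value per distinct domain.

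The interval code was checked against bedtools 2.31.1 and gave the same overlaps. The tests were tested on simulated data, 24 lists of 15 genes each. With no difference built in, 0 lists were called by share or width. With domains made 2-fold wider or narrower, 24 and 23 lists were called by width. With far fewer genes marked, independently of CpG content, 23 were called by share. Smaller shortfalls, such as those of the ependyma, muscle and pluripotency lists, were not simulated. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.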

Results

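Trimethylation of lysine 4 on histone H3 (H3K4me3), a mark found mainly at active and poised promoters, was mapped by chromatin immunoprecipitation and sequencing in whole mouse midbrain at embryonic day 14.5. The samples formed 1 group of 2 biological replicates, each pooled from embryos of both sexes: 24 embryos in replicate 1 and 34 in replicate 2. Per replicate the values used were lists of peaks, so the read depth of each library is unknown, and the number of peaks stands in for it. Replicate 1 had 26711 peaks covering 36.0 Mb and replicate 2 had 29771 peaks covering 36.8 Mb. The authors' list of replicated peaks held 21806 peaks covering 38.5 Mb of mm10, with a median width of 1546.5 bp. Positions are 1-based on mm10. The group had no contrasting condition, so each comparison below is within these libraries: replicate against replicate, peaks against random placements, and gene lists against other genes.

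The replicates shared their strong peaks and differed in their weak ones. Of the replicate 1 peaks, 86.2% (Wilson 95% interval 85.8 to 86.6%) overlapped a replicate 2 peak by at least 1 bp, against 2.73% when the peaks were placed at random. Of the replicate 2 peaks, 78.7% (78.3 to 79.2%) overlapped a replicate 1 peak, against 2.55% at random. The 3694 replicate 1 peaks with no partner had a median fold enrichment of 3.07, against 20.4 for those with one; the 6331 unpartnered replicate 2 peaks had 3.23 against 20.8. In replicate 1 the overlap rose from 40.9% in the weakest strength decile to 100% from decile 5 upward. In replicate 2 it rose from 24.8% to 98.1% in decile 5 and 100% from decile 6 upward. These and all other intervals cover counting error only. Fold enrichments and significance scores are the authors' values per peak and serve here only to rank or describe peaks within a list. Their ranks across overlapping peaks gave a Spearman correlation of 0.713, and the widths of promoter domains gave 0.935 across 14208 genes marked in both replicates, on data in which neither peaks nor genes are independent replicates.

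**Figure D1:**
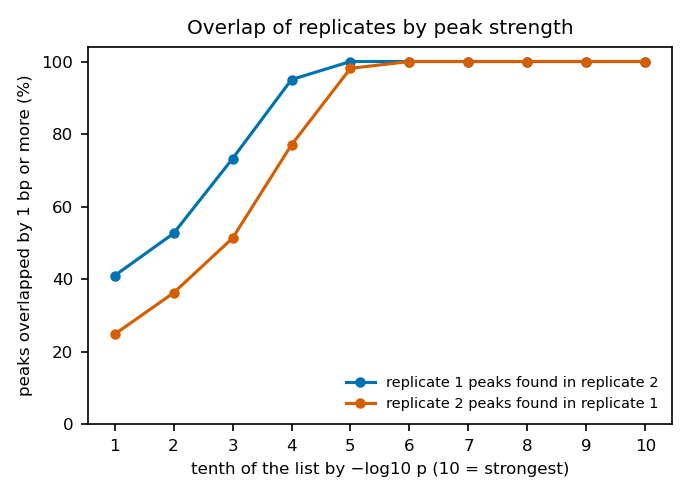
Percent of the peaks of each replicate overlapped by at least 1 bp in the other (vertical axis) by strength decile of −log10 p (horizontal axis, 10 the strongest). Both lines reach 100% by decile 6, and the weakest decile lies at 40.9% for replicate 1 and 24.8% for replicate 2.

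Replicated peaks lay mostly at promoters. Of 21790 peaks on assembled chromosomes, 73.3% (72.7 to 73.9%) came within 1 kb of an annotated transcription start site (TSS), against 10.6% for random placements. The share was 66.1% in the list of replicate 1 and 62.1% in that of replicate 2. Starts of protein-coding genes accounted for 68.0% of the replicated peaks and starts of other genes for 5.27%. The rest overlapped exons (4.74%) or introns (9.95%) away from any TSS, or lay between genes (12.04%). Peaks at a TSS had a median width of 1912 bp and a median fold enrichment of 41.6. The 3311 peaks (15.2%) more than 5 kb from every annotated TSS were narrower and weaker, with medians of 664 bp and 5.81.

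A few of these distant peaks were as strong as promoter peaks. The strongest, between genes on chromosome 1 at 171037651 to 171039076, had a fold enrichment of 62.1. Next came a peak of 58.1 in an intron of the long noncoding RNA gene Lncppara (chromosome 15, 85669628 to 85674936) and a peak of 56.5 on chromosome 9 at 32031341 to 32034620. The latter lay within 1 kb of a RefSeq start of Arhgap32, a Rho GTPase-activating protein gene, that the annotation used for the counts lacks. A peak of 54.1 on chromosome 4 at 46304233 to 46305829, in an intron of Gm12446, lay at a RefSeq start of Gm12447. A peak of 53.7 on chromosome 12 at 8640336 to 8641806 had Pum2, an RNA-binding protein gene, as its nearest annotated start at 32.3 kb. The last of the 6 strongest, at 53.5, was between genes on chromosome 17 at 22080348 to 22081661. Each of the 6 was found in both replicates.

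Most protein-coding genes carried the mark at a promoter: 14253 of 21911 genes, or 65.0% (64.4 to 65.7%). The separate lists gave 65.3% in replicate 1 and 65.7% in replicate 2, and 14196 of the 14253 genes were marked in both. The strongest promoter peak of the replicated list was that of Actb, the gene of beta-actin, with a fold enrichment of 84.9 in the replicated list, 73.2 in replicate 1 and 70.0 in replicate 2, where other peaks reached up to 76.5. It was followed by Usp22, a deubiquitinase of the SAGA complex, at 84.7, by Clk1, a kinase of splicing factors, at 83.9, by the adaptor gene Traf4 at 82.9 and by the transcription factor gene Sp3 at 82.3. Arid1a (a chromatin remodeller subunit), Hsp90ab1 (a chaperone) and the neighbouring pair Rnf114 and Spata2 all had 81.9. Ubc, a polyubiquitin gene, shared its peak with Gm10382 at 81.2, and Clptm1 had 81.1. These last peaks differed between replicates: Clptm1 had 42.8 in replicate 1 and 72.9 in replicate 2, and Ubc 55.5 and 71.5. The median over marked genes in replicate 1 was 38.1. The other genes named here had at least 58.3 (Sp3) in replicate 1. The mark followed promoter sequence closely: 5.57% of genes in the lowest decile of promoter CpG content (observed over expected) were marked and 99.5% of those in the highest.

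All members of 9 of the 24 gene lists fixed in advance were marked, and each of these lists was marked more often than other protein-coding genes. They were the lists of midbrain and isthmus patterning (15 of 15 genes, among them the homeobox genes Otx2 and Meis2), GABAergic neurons (12 of 12, with Gata3 and Lhx1), glutamatergic neurons (15 of 15, with Ebf3 and Lhx9) and pan-neuronal genes (18 of 18, with the RNA-binding protein genes Elavl4 and Celf4). The others were neural progenitors and radial glia (20 of 20, with Sox2 and Msi1), late synaptic maturation (13 of 13, with the neurotrophin gene Bdnf and the potassium channel gene Kcna1), cell cycle (18 of 18, with the cyclin genes Ccnd1 and Ccnd2), housekeeping (20 of 20, with Polr2a and Eef1a1) and forebrain patterning (21 of 21, with Lhx2 and Emx2). About 65.0% of the genes outside each of these lists were marked. Adjusted p ranged from 0.000880 for progenitors, housekeeping and forebrain genes to 0.0193 for GABAergic genes (Fisher exact test per list, two-sided, Benjamini-Hochberg over the 24 lists; genes are the units and are not independent replicates). Wnt1, the signalling gene of the midbrain-hindbrain boundary, was marked in the list of replicate 1 and not in that of replicate 2, and the midbrain list had an adjusted exact p of 0.0494 in replicate 2 with 14 genes marked; Wnt1 was singled out after its values were seen. The GABAergic call ended when only the 5′ end of each gene served as its TSS (adjusted exact p = 0.0582). Against random lists matched on promoter CpG content, only the glutamatergic (adjusted permutation p = 0.0219; 81.3% of matched genes marked) and pan-neuronal lists (0.000720; 72.2%) remained called. This matching took CpG content at the gene 5′ end but marking at any start. With 5′ ends alone, the pan-neuronal excess over other genes was 27.4 points (adjusted exact p = 0.0306). The lists that lost their call were already fully marked, so no share could have kept it. Matched genes were marked at 96.3% for cell cycle and 93.2% for midbrain genes.

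Genes of microglia, erythroid cells, liver, germ cells and sensory receptors were seldom marked. Among microglial genes 1 of 15 was marked, the lysosomal enzyme gene Hexb (adjusted exact p = 3.26e-05, as for the p in brackets after it), and Aif1 and C1qa were not. None of 16 liver genes was (5.89e-07), including Alb and Ahsg, with a Wilson upper limit of 19.4%. Spermatogenesis had 2 of 15 genes marked (0.000332), Dazl and Dmc1, whereas Ddx4 and Acrv1 were unmarked. Of 1464 olfactory and vomeronasal receptor genes 3 were marked (0.205%, interval 0.0697 to 0.601%), with an adjusted p too small for the software to hold. These were Vmn1r4, whose domain also covers the start of Nt5c3, together with Olfr94 and Olfr658; the unmarked ones included Olfr1 and Olfr10, and Olfr658 was named after its values were seen. Erythroid genes had 5 of 15 marked (0.0222): Sptb and the transferrin receptor gene Tfrc were, and the heme synthesis gene Alas2 and Ermap were not. The erythroid call ended without replicate 1 (6 of 15, adjusted exact p = 0.0854) and with 5′ ends alone (0.0560). Against CpG-matched lists the calls for microglia (adjusted permutation p = 0.100; 29.1% of matched genes marked), liver (0.0706; 23.5%) and erythroid genes (p = 1; 34.1%) ended, while spermatogenesis (58.6% of matched genes marked) and the receptors (13.2%) kept theirs at 0.000160 each.

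The dopaminergic list stood between these groups. Of its 14 genes 11 were marked (78.6%, interval 52.4 to 92.4%; adjusted exact p = 0.510), with the widest domains at the nuclear receptor gene Nr4a2 (8.42 kb) and the pioneer factor gene Foxa1 (5.96 kb). Foxa1 was narrower in the single lists, at 4.13 kb in replicate 1 and 3.05 kb in replicate 2, and in replicate 2 Foxa2 (4.27 kb) and Msx1 (3.49 kb), named after their values were seen, were wider than Foxa1. Aldh1a1, Ddc and Th, the genes of a retinaldehyde dehydrogenase, of aromatic amino acid decarboxylase and of tyrosine hydroxylase, had no replicated promoter peak; Th was named after its values were seen. Ddc had a peak of 0.210 kb in replicate 1 alone, and Aldh1a1 and Th had none in either replicate. The transporter genes Slc6a3 and Slc18a2 and the transcription factor gene Pitx3 were marked in both replicates, over 1.52, 1.20 and 1.99 kb. They were likewise picked after their values were seen. The Pitx3 domain (chromosome 19, 46135458 to 46137446) lay at another annotated start, downstream of the gene 5′ end at 46148326. So did the Nr4a2 domain (chromosome 2, 57109340 to 57117757), with the gene 5′ end at 57124003.

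For 8 further lists, of glial, vascular, meningeal, motor, muscle and pluripotency genes, no difference from other genes passed the test. The oligodendrocyte lineage had 9 of 15 genes marked (adjusted exact p = 0.822; Olig2 and Nkx2-2 marked, the later myelin gene Mag and Gpr17 not). Astrocytes had 7 of 12 (0.822; Slc1a2 and Fgfr3 marked, Agt and Aldoc not). Endothelium and pericytes had 12 of 18 (adjusted exact p = 1; Pdgfrb and Ets1 marked, Pecam1 and Emcn not) and meninges and mesenchyme 11 of 15 (0.682; Prrx1 and Foxc1 marked, Col3a1 and Dcn not). Cranial motor and serotonergic neurons had 8 of 10 (0.612; Chat and Slc18a3 marked over a shared domain, Phox2b and Tph2 not). Muscle had 7 of 15 (0.233; Mylpf and Ryr1 marked, Acta1 and Actc1 not) and pluripotency 6 of 13 (0.224; Lin28a and Esrrb marked, Dppa3 and Dppa4 not). Ependyma and choroid plexus had 5 of 12 (0.190; Foxj1 and Lmx1a marked, Aqp1 and Calml4 not); with 4 of 12 marked it was called less often marked without replicate 1 (0.0497), without replicate 2 (0.0483), at a −log10 q of at least 5 (0.0481) and with only peaks shared with both replicates (0.0476). How many genes of these cell type lists the midbrain itself expresses was not analysed here. Lmx1a, Six3, Tfrc and Pdgfra each stand in more than 1 list.

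**Figure D2:**
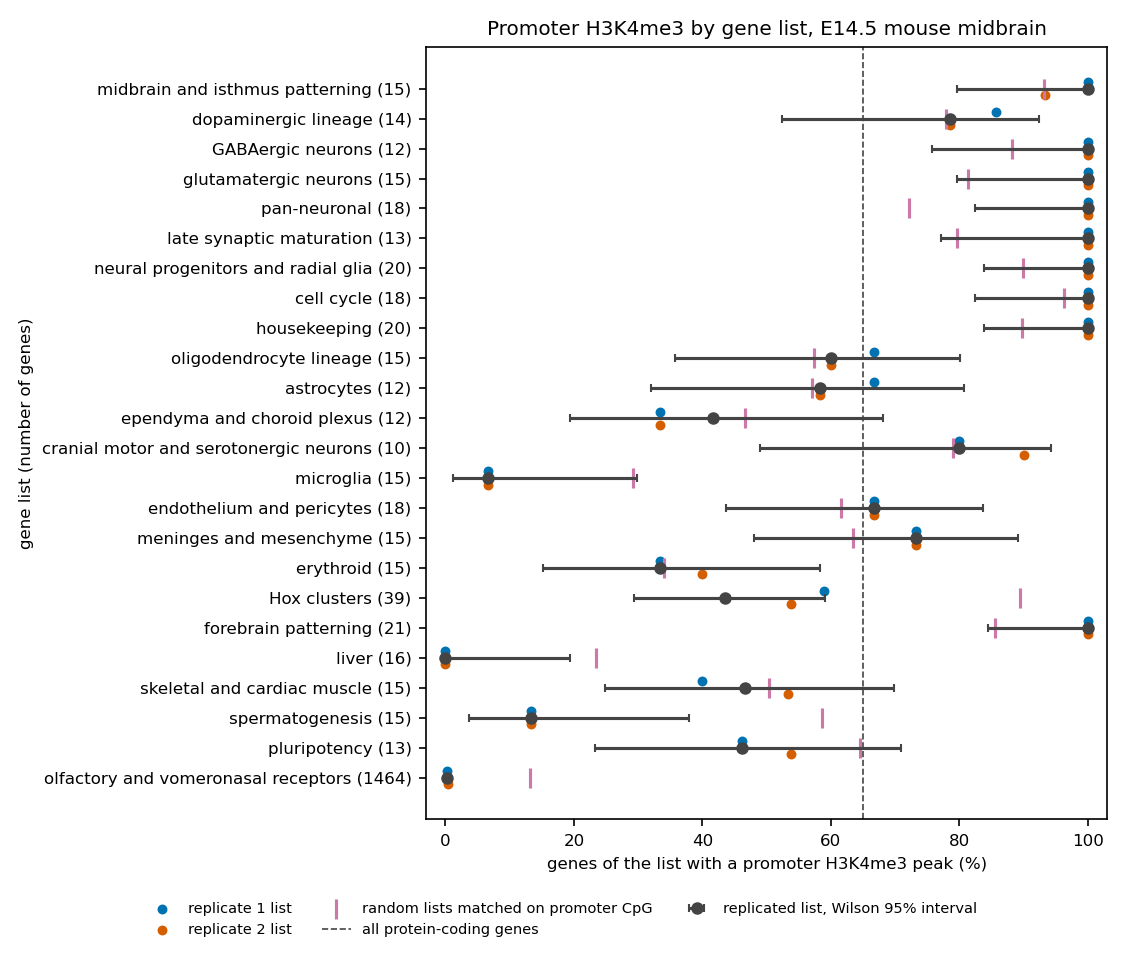
Percent of the genes of each list with a promoter H3K4me3 peak (horizontal axis) for the 24 lists, with the list size in brackets, for the replicated list with Wilson 95% intervals, each replicate, and random lists matched on promoter CpG content. The dashed line marks all protein-coding genes at 65.0%; 9 lists lie at 100% and the liver list at 0%.

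Hox genes, which pattern the body axis from the hindbrain backward, were marked seldom and over narrow domains. Of 39 Hox genes 17 were marked (43.6%, interval 29.3 to 59.0%; adjusted exact p = 0.0123), with Hoxa10 and Hoxa11 among the unmarked. CpG-matched random lists were marked at 89.5%, and the difference from them had an adjusted permutation p of 0.000160. Against all other genes the call ended without replicate 1 (21 of 39, adjusted exact p = 0.195), without replicate 2 (23 of 39, 0.511), with pooled peaks (25 of 39, 0.990) and with a TSS window of 2 kb (0.193), so the number of marked Hox genes depends on the peak list. Their width was called under each alternative, at 0.242 to 0.353 times random lists. Random lists matched on peak strength, a further comparison, left a ratio of 0.626 (adjusted permutation p = 0.00731). The marked Hox genes had a median domain of 0.640 kb, 0.291 times the median of random lists, and all 17 lay below that median (two-sided permutation test, adjusted p = 6.67e-05). The list medians of the replicates, over the 23 Hox genes marked in replicate 1 and the 21 in replicate 2, averaged 0.520 ± 0.0205 kb (SD, n = 2). The widest Hox domains were at Hoxd1 (1.42 kb) and Hoxd8 (1.40 kb), and the median fold enrichment of the marked Hox promoters was 4.38.

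**Figure D3:**
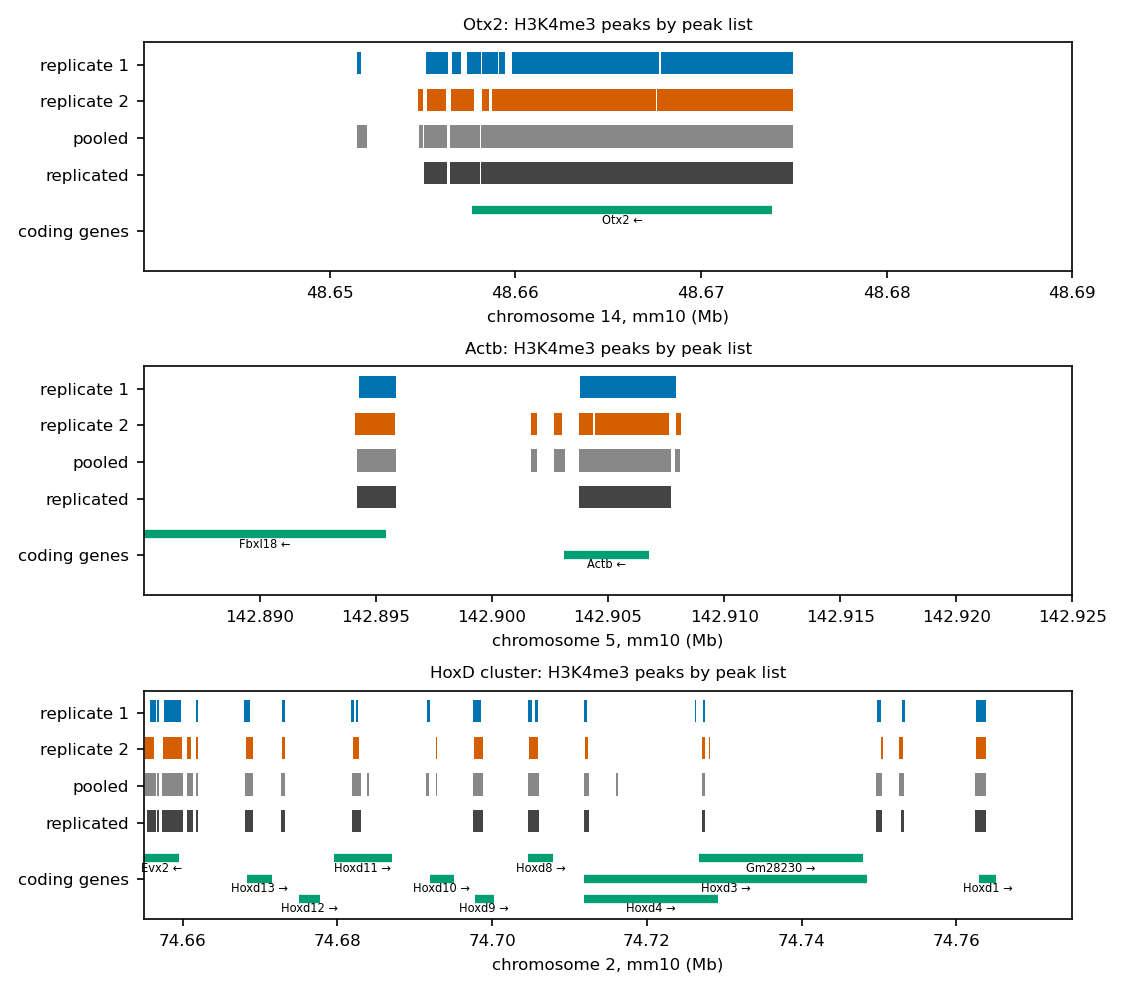
Peaks of each list (bars, by row) and protein-coding genes (green, arrows give the strand) along mm10 in Mb at Otx2, Actb and the HoxD cluster, each panel to its own scale. Otx2 is covered over 19.9 kb and Actb over 3.94 kb, and the Hoxd1 domain spans 1.42 kb.

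The 12 widest promoter domains at protein-coding genes included those of Nr2f2, Pou3f3, Meis2 and Otx2. Over all marked genes the median domain was 2202 bp. The nuclear receptor gene Nr2f2 had 25.1 kb (chromosome 7, 70345680 to 70370759; replicates 20.6 ± 5.92 kb, mean ± SD, n = 2 here and for the genes after it) and the POU-domain gene Pou3f3 24.5 kb (chromosome 1, 42683930 to 42708468; 21.9 ± 0.112 kb). Ebf3, a helix-loop-helix factor gene, had 23.1 kb (22.6 ± 0.559 kb) and Meis2 21.4 kb (chromosome 2, 116055008 to 116076364; 21.3 ± 0.0587 kb). Otx2, required for the formation of forebrain and midbrain, had 19.9 kb (chromosome 14, 48655097 to 48674974; 20.0 ± 0.291 kb). Lhx2 had 21.8 kb in the replicated list and 12.3 ± 2.57 kb in the replicates, and Zfhx3 20.1 kb and 16.6 ± 4.82 kb, at an internal start of the gene (chromosome 8, 108699333 to 108719407). Gata3 had 19.5 kb, shared with 4930412O13Rik and 9230102O04Rik. The LIM-homeobox genes Lhx9, Lhx1 and Lhx5 had 18.9, 18.4 and 17.3 kb, and Mn1 had 16.3 kb. Across genes the log2 ratio of replicate 1 to replicate 2 width had a median of −0.01 and an SD of 0.28.

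By gene list, domains were widest at the GABAergic, midbrain and isthmus, and glutamatergic genes. Of 20 lists with at least 5 marked genes, 6 had wider domains than random lists of marked genes. GABAergic genes had a median of 9.72 kb, 4.40 times that of random lists (replicates 9.46 ± 0.398 kb, SD, n = 2), with 12 of 12 genes above the random median and 10 in the top 5% of all marked genes. Midbrain and isthmus genes had 7.60 kb, 3.45 times (6.44 ± 0.398 kb), with 12 of 15 above. When only the 5′ end of each gene served as its TSS, their ratio was 2.29, below the 2.80 of progenitor genes. Glutamatergic genes had 6.59 kb, 2.99 times (6.23 ± 0.193 kb, 13 of 15 above), progenitor genes 5.54 kb, 2.52 times (5.12 ± 0.519 kb, 20 of 20), and pan-neuronal genes 4.71 kb, 2.14 times (4.57 ± 0.0714 kb, 18 of 18). In the replicated list, Sox2 led the progenitors with 12.5 kb and Msi1 followed with 11.9 kb. Elavl4 and Celf4 led the pan-neuronal genes there with 9.58 and 9.56 kb. For these 5 lists p was 2e-05, the smallest that 100000 random lists can give (two-sided permutation test), and adjusted p was 6.67e-05. In a comparison added to those fixed in advance, the median fold enrichments of the midbrain (21.5), GABAergic (23.0) and glutamatergic lists (29.6) lay below the central 95% of random lists, and those of the progenitor (38.2) and pan-neuronal lists (48.3) within it. A low fold enrichment was not particular to lists with wide domains: most of the 20 lists lay below that range, among them dopaminergic (14.9) and endothelial genes (12.6).

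Forebrain and muscle genes also passed the width test, less firmly. Forebrain genes had 3.01 kb, 1.37 times random lists (13 of 21 above the random median, replicates 2.41 ± 0.329 kb, SD, n = 2; permutation test, adjusted p = 0.0243), led by Lhx2 and by Emx2 at 9.92 kb. That call ended without replicate 1 (ratio 1.27, adjusted permutation p = 0.101), without replicate 2 (1.05, 0.819), at a −log10 q of at least 5 (0.0855) and when only overlapping peaks were merged (0.595). Muscle genes had narrow domains of 0.945 kb, 0.428 times (6 of 7 below, 1.04 ± 0.257 kb; permutation test, adjusted p = 0.00257), and the call ended without replicate 2 (0.584 times, adjusted p = 0.0630). The widest muscle domain, Mylpf at 3.86 kb, also covers the start of Tbc1d10b. Against random lists matched on peak strength, forebrain genes had 2.84 times (adjusted permutation p = 6.67e-05). Muscle genes had 0.745 times, and their call ended (0.357).

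The other 12 lists tested did not pass the width test in the replicated list. Cell cycle and housekeeping genes had 2.62 and 2.68 kb (1.19 and 1.21 times random lists; adjusted permutation p = 0.253 and 0.197), with Ccnd2 at 7.58 kb (7.49 kb in replicate 1 and 4.84 kb in replicate 2) and Polr2a at 5.25 kb. Dopaminergic genes had 1.99 kb (0.903 times, 0.573) and late synaptic genes 1.89 kb (0.859 times, 0.399), with Bdnf at 5.78 kb. Glial and support lists gave 2.57 kb for astrocytes (adjusted permutation p = 0.492), 1.66 kb for oligodendrocytes (0.214), 1.45 kb for ependyma (0.191), 1.96 kb for endothelium (0.492) and 2.04 kb for meninges (0.636). Cranial motor genes had 1.75 kb (0.275) and erythroid genes 1.57 kb (0.253). Pluripotency genes had 1.40 kb (0.633 times, adjusted permutation p = 0.0865) and were called narrower without replicate 1 (0.459 times, 0.00729).

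**Figure D4:**
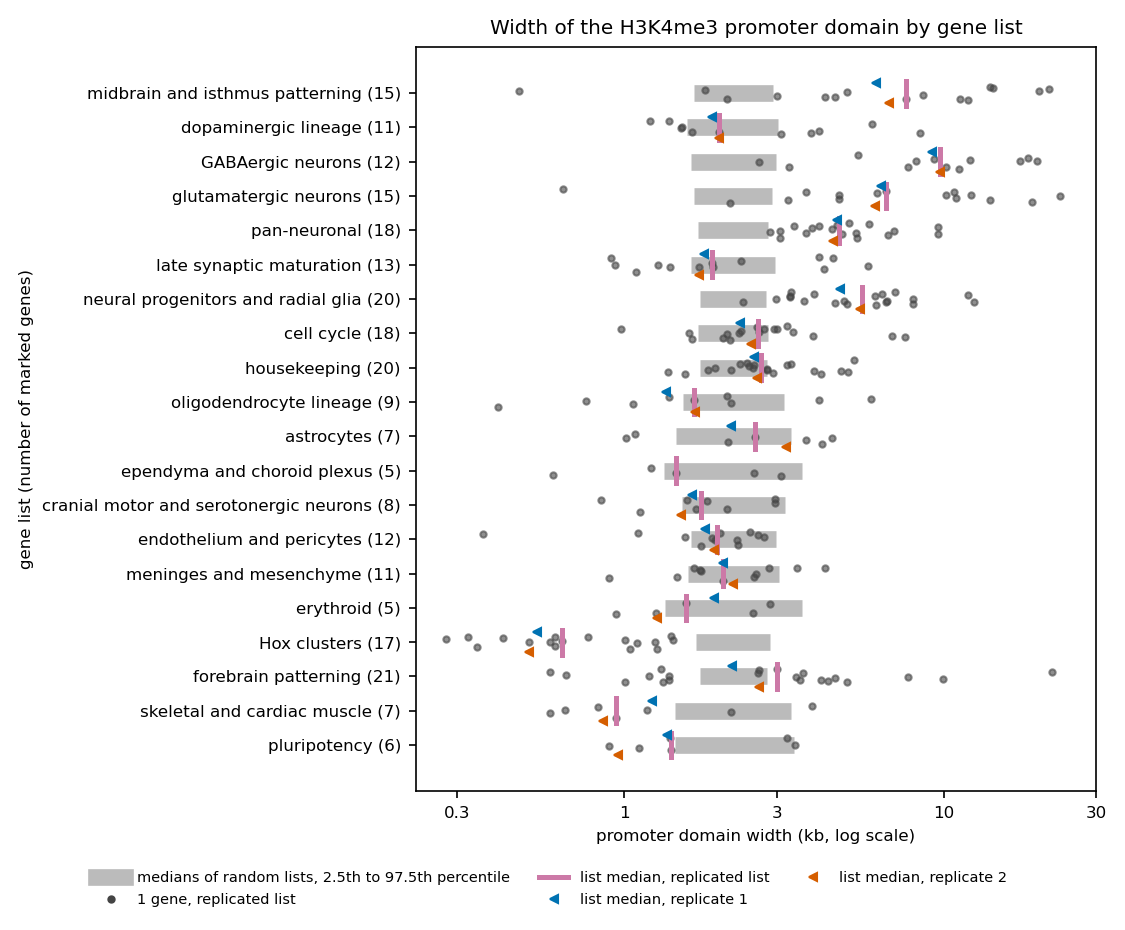
Width of the promoter H3K4me3 domain in kb (horizontal axis, log scale) for the 20 lists with at least 5 marked genes: points are genes, bars and triangles are list medians in the replicated list and each replicate, and grey boxes span the central 95% of the medians of random lists. The GABAergic median lies at 9.72 kb and the Hox median at 0.640 kb, outside their boxes.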

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

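The test of hindbrain cells was chosen only after the result it measures was seen; matching on CpG content was chosen beforehand, but the limits by which it is read here, for the wide lists and for Hox genes, were set after its values were seen.

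Outside the chromosomes used for the comparisons, 16 replicated peaks lay on 6 unlocalized or unplaced scaffolds, above the limit of 3 set for a closer look. No number of peaks was predicted there, so the count is no test of an excess. Of these, 14 overlapped peaks of both replicates and 5 were at annotated starts, including Vamp7, a vesicle fusion gene, and Tmlhe, an enzyme gene of carnitine synthesis. Their median fold enrichment was 6.93 and the highest was 35.8.

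Promoter domains of the GABAergic, midbrain, glutamatergic, progenitor and pan-neuronal lists were 2.14 to 4.40 times as wide as those of random lists. Random lists matched on promoter CpG content left ratios of at least 2.26. Those matched on the number of annotated starts left at least 2.11, and those matched on peak strength at least 2.03. Adjusted p was at most 6.67e-05 in each (permutation tests), which argues against these properties, as measured, as the whole cause. CpG content was measured only within 500 bp of the gene 5′ end, so CpG content along the rest of a wide domain was not tested. A biological explanation, that wide domains mark genes of cell identity in this tissue, may account for the pattern, but only as a hypothesis: no other tissue or age was analysed here. Not all lists go with it. The dopaminergic list, also of midbrain cells, was not called wider (0.903 times, adjusted permutation p = 0.573). Forebrain patterning genes were called wider, less firmly (1.37 times, 0.0243). Among the other lists, matching on peak strength called forebrain (2.84 times) and endothelial genes wider and only Hox genes narrower. Endothelial genes had 1.62 times (adjusted permutation p = 0.0476). How the peak caller joins neighbouring peaks stays open beyond the merging distances tried.

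Few Hox promoters were marked, and those marked had narrow domains. Against random lists matched on peak strength these domains were 0.626 times as wide (adjusted permutation p = 0.00731), so part of the narrowness went with weak peaks. CpG content at the gene 5′ end is argued against as the cause of the low share, since the upper 95% limit of 59.0% stayed below the 89.5% of matched genes. Loss in the replicate filter is argued against as the whole cause in the same way, since in the pooled list, before that filter, the upper limit was 77.3% (25 of 39 genes marked) against 90.1%. Cells of the neighbouring hindbrain, where paralogue groups 1 to 4 are used, could supply the marked genes of those groups. That would leave the 11 marked genes of groups 5 to 13 open. Groups 1 to 4 (6 of 12 marked) and 5 to 13 (11 of 27) gave a Fisher exact p of 0.730, two-sided, too few genes to decide. Silencing of Hox genes in the midbrain, the biological candidate, was not tested.

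Some peaks more than 5 kb from every annotated TSS were strong, and the 6 strongest stood in both replicates. Among the 827 strongest of them, 18.4% (15.9 to 21.2%) lay within 1 kb of a RefSeq start, against 1.32% for random placements, so missing starts could account for part of them; the share fell between the limits of 10% and 25% set beforehand and leaves the rest open. Overlap with annotated pseudogenes was 0.121%, but choosing peaks far from annotated starts, those of pseudogenes included, removes most such overlaps, so this test was judged void after its value, under the limit set beforehand, had been seen. Reads shared with gene copies therefore cannot be told apart from other sources. No biological explanation was tested.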

How the results depend on the processing

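Replicated peaks sharing a base with both replicates, and 1 value per distinct domain, were alternatives chosen after seeing the data. Overlap of replicate 1 and of replicate 2 peaks changed to 80.2% and 72.8% with 50% of the peak shared, 73.4% and 65.9% with 50% of both, 94.8% and 94.5% at a −log10 q of at least 5, and 84.8% and 84.97% with equal numbers of peaks. The share at a TSS changed to 77.8% (2 kb window), 63.4% (5′ ends), 62.7% (pooled) and 76.4% (−log10 q of at least 5), and was 62.1 to 66.1% without either replicate. The share of genes marked changed to 64.6% (500 bp window), 65.8% (2 kb), 61.5% (5′ ends), 65.9% (pooled), 64.7% (−log10 q) and 63.6% (summits), and was 65.3 to 65.7% without either replicate. Lists more often marked fell from 9 to 2 and lists less often marked from 6 to 3 with CpG-matched lists. Otherwise they numbered 8 to 9 and 5 to 7. The matched setting also replaced the exact test by a permutation test, and no unmatched permutation test of shares was run. For each list that lost its call, however, matching moved the reference share toward that of the list. It went from about 65.0% to between 79.6% (late synaptic) and 96.3% (cell cycle) for the fully marked lists. For microglial, liver and erythroid genes it went from 65.1% to between 23.5% (liver) and 34.1% (erythroid). These values argue against the change of test as the whole cause of the lost calls. How much each change contributed was not tested. Lists with wider domains numbered 5 to 6. Those with narrower domains numbered 4 without replicate 1, where pluripotency genes passed and the olfactory receptors had enough marked genes to be tested, and 1 without replicate 2. Width agreement changed to 0.920 (merging at 1 kb) and 0.951 (−log10 q), and strength agreement to 0.941 (50% of both peaks), 0.832 (−log10 q) and 0.733 (−log10 p); unless stated, causes were not tested. Across settings, for single lists tested in the main setting, 227 width results stayed on their side of the threshold, 5 lost and 1 gained a call. The olfactory receptors, whose widths were not tested in the main setting, are not in this count. For shares the counts were 195, 17 and 4, and no called direction of width or share reversed. The GABAergic, midbrain, glutamatergic, progenitor and pan-neuronal lists stayed wider, and the Hox list narrower, in all 13 settings, main included. The read depth is unknown, so a peak missing from a list does not show that the mark was absent.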

Other observations

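The microRNA, gene family and gene type values here were all chosen after the data had been seen. The widest domain of all 19741 domains belonged to no protein-coding gene: it spanned 29.5 kb (chromosome 13, 83713507 to 83742965; replicates 28.8 ± 0.779 kb, SD, n = 2) at Mir9-2, a microRNA of neural progenitors and neurons, and its host transcript C130071C03Rik. All 6 loci of the neural microRNAs Mir9 and Mir124 were marked, with 17.5 kb at Mir124a-2, 12.4 kb at Mir9-1 and at Mir9-3, 9.78 kb at Mir124a-1 and 8.39 kb at Mir124a-3. Their median of 12.4 kb was 4.51 times that of random lists of marked microRNA genes (2.76 kb; two-sided permutation test, p = 6e-05). The list was formed after the Mir9-2 domain was noticed, so this p is not independent evidence. Malat1, a nuclear long noncoding RNA gene, had 9.62 kb.

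Among 167 gene families with at least 10 marked genes, defined by the stem of the symbol, 5 had more members in the top 5% of widths than other genes (Fisher exact test, two-sided, adjusted over the families; 13 had an unadjusted p under 0.05). Protocadherins outside the clustered Pcdha, Pcdhb and Pcdhg genes, adhesion molecules of neurons, had 9 of 11 (adjusted exact p = 1.57e-08), with 11.7 kb at Pcdh10, 11.3 kb at Pcdh7 and 10.4 kb at Pcdh19, and none of the 9 stands in a fixed list. The clustered Pcdhga genes had 0 of 12. Sox genes had 10 of 17 (1.09e-07; 6 of the 10 in fixed lists), Pou genes 6 of 11 (0.000318; 1 of the 6), Frizzled receptor genes 5 of 10 (0.00263; none) and Arid genes 4 of 10 (0.0342; none).

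Outside protein-coding genes, 14.5% of 5854 long intergenic RNA genes and 34.8% of 2959 antisense genes had a promoter peak. The share was 92.6% of 190 genes annotated as noncoding partners of a bidirectional promoter. Any peak within 1 kb counted, so that share may reflect the peaks of their coding partners. Processed pseudogenes, copies of spliced transcripts, were marked in 1.64% of 9940. No member of the families of beta-defensins (0 of 42), secretoglobins (0 of 34) or major urinary proteins (0 of 22) was marked. Their Wilson upper limits were 8.38, 10.2 and 14.9%. Their promoters were poor in CpG, with medians of 0.116, 0.117 and 0.129. Of all protein-coding genes in the 2 lowest CpG deciles, 5.57% and 11.7% were marked, so these absences are not particular to the families.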
